A study of Homo sapiens with 22 samples.

How the data were processed

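RNA was sequenced from neural progenitor cells derived from GM8330-8, a human induced pluripotent stem cell line, at passage 7, after lentiviral delivery of short hairpin RNAs (shRNAs) against the chromatin remodeller CHD8 or against GFP and LacZ, sequences that human cells do not carry. Per the labels' protocols, puromycin selection followed transduction, total RNA was extracted with TRIzol and chloroform, and strand-specific dUTP libraries with synthetic spike-in RNAs were sequenced as read pairs. The labels list 22 libraries, 14 with a CHD8 shRNA and 8 controls, in 2 batches of infection and sequencing, with technical replicates a and b of each infection. Values of 17 libraries, 10 knockdown and 7 control, were used. They stand for 9 infections: shRNA 4, shRNA 6, GFP and LacZ in batch 1, and shRNA 2, shRNA 5, shRNA 6, GFP and LacZ in batch 2. The LacZ infection of batch 1 has 1 library here. The other 5 libraries, among them those of 2 further CHD8 shRNAs, were not analysed here.

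The authors deposited 1 table with a row for each of 15903 genes. Per the file headers, it gives the authors' FPKM of each library (fragments scaled by transcript length and library size). It also holds log2 CPM (counts scaled by library size) of each library, per the file headers, with a small prior count that the authors added. The values themselves show that the authors had removed 1 batch coefficient per gene from these log2 CPM, and no label records this step. Its shifts are those of centring over the control libraries used here, but not over the 10 knockdown libraries used here. Among knockdown libraries, the shift of batch 1 was -2.0 times that of batch 2. The authors' centring and comparison may thus rest on knockdown libraries that were not analysed here. The authors' log2 fold change of knockdown over control, their p-value and their adjusted p-value are further columns, per the file headers, and the deposited adjusted p-values equal a Benjamini-Hochberg adjustment over the whole table. The submitters' processing notes name the genome build GRCh37 and the tools FastQC, bedtools 2.17.0, DESeq 1.12.1, edgeR and Cufflinks, with no role or order. The aligner, the gene annotation, and the model and covariates of the authors' comparison are not given in the sources used here. FPKM divides by library size and transcript length, so a few abundant or GC-rich transcripts that take more of a library lower the values of all others, and reads of overlapping or near-identical genes are shared out by an estimate.

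FPKM was missing for 28 genes, which left 15875 genes tested. There were 7 genes not marked as converged by the authors; these stayed in. A symbol with more than 1 row (125 symbols) entered a gene list with the row of the highest mean level. The design assumed counts; because the deposited values are normalised, the test laid down for that case was used. FPKM was averaged over the technical replicates of an infection, 1 was added, and log2 was taken, so a fold change on this scale understates that of low genes. No filter on low values was applied. The fits were made with limma (trend and robust options) on 1 value per infection, with batch as a covariate and with Benjamini-Hochberg adjustment at 0.05. The infection was the replicate, 5 knockdown against 4 control. Nothing in the labels says that infections came from separate cultures, and all came from 1 line, so p-values measure only the spread between these infections. The comparisons were CHD8 knockdown against control over both batches, the same within each batch, the interaction of knockdown with batch, GFP against LacZ among the controls, and the correlation across genes of the fold changes of shRNA 6 in the batches. CHD8 alone was also tested by a two-sided exact permutation of the infections within batches. Fold changes of single infections were taken against the mean log2 level of the controls of the same batch.

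The comparisons, the gene lists and the rule for named genes were fixed before the data were examined. The rule named CHD8 first. It then named up to 12 genes per direction among those past the adjusted threshold, filled in order of p from those at an unadjusted p under 0.05, where the mean level reached the median of the genes tested (8.28 FPKM) and at least 4 of the 5 knockdown infections moved the same way. From each list, the up to 4 members with the smallest p were added. Some genes that the rule names are not reported here. The 25 lists comprise autism spectrum disorder (ASD) risk genes, Wnt signalling, p53 targets, cell cycle, axon guidance, synapse and ion channels, cell adhesion and cadherins, extracellular matrix, chromatin regulators, Notch and Hedgehog signalling, microcephaly and centrosome genes, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, interferon response, unfolded protein and integrated stress response, cholesterol biosynthesis, the CHD family, HOX genes, and markers of neural progenitors, neurons, glia, neural crest and mesenchyme, and pluripotency. None of the 26 HOX genes had a row, so 24 lists were tested. Lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, two-sided, adjusted over the lists. Genes are not independent replicates.

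Sequencing depth was recovered from the log2 CPM of the authors: with the prior count of each library searched for as the value that makes low genes whole and the batch step undone, 15893 of the 15903 genes gave read counts in each library. Of the values under 1000 reads, 100.0% were whole within 0.05, where 7.9% would be with the prior count off by 1 percent, and the smallest count was 4. Library totals ran from 33.4 to 88.9 megareads (median 65.4). These recovered reads are a reconstruction and served only for depth and for an alternative fit.

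Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, filters on the mean level, no batch term, technical replicates as separate libraries, leaving out each infection in turn, shRNA 6 of batch 1 only, GFP or LacZ controls only, and other thresholds. Alternatives chosen after seeing the data were the deposited log2 CPM, limma-voom on the recovered reads scaled by their upper quartile, FPKM scaled to an equal upper quartile, FPKM with the trend of each infection with transcript GC content removed (lowess span 0.3, genes with a mean of 1 FPKM or more, 0.01 added), the technical replicate letter as a block, the infection as a random effect, and leaving out both shRNA 6 infections. Transcript GC content and exonic length came from GENCODE release 29, used only as gene properties and not for coordinates, since its build differs from GRCh37.

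The fits of the comparisons, and those on the deposited log2 CPM, on recovered reads, with the infection as a random effect and without the GC trend, were tested on simulated data with the real means and spread, 200 genes of them changed. Simulated errors were independent between genes, whereas the correlation estimated within the real lists reached 0.793. The false calls and list calls below are thus no check against correlated genes. The comparison of knockdown with control found 20.9% of the 67 genes simulated at 1.5-fold, 55.2% of 67 at 2-fold and 89.4% of 66 at 4-fold, with 7 false calls among 15875 genes. The interaction found 40.9% of the 4-fold changes, batch 2 alone 62.1%, and batch 1 alone and GFP against LacZ 0% each. Limma-voom on simulated reads of 15893 genes found 63.6% at 4-fold. The comparison of knockdown with control found 92.4% at 4-fold on log2 CPM of 15903 genes, 97.0% with the infection as a random effect over 15875 genes, and 93.8% with the GC trend removed over 15451 genes. The interaction with the GC trend removed found 60.9% at 4-fold over 15451 genes. The other alternatives were not simulated. A list of genes shifted by -0.2 on the log2 scale was called, as was 1 other list. The recovery of reads, given no prior counts, returned 99.9% of the simulated reads of 4000 genes. The tools were R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.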

Results

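The effect of lowering CHD8, an ATP-dependent chromatin remodeller of the chromodomain helicase family, on the transcriptome of human neural progenitor cells was measured by RNA sequencing. The cells were derived from the induced pluripotent stem cell line GM8330-8 and carried an shRNA against CHD8 or, as controls, against GFP or LacZ. There were 5 knockdown infections, 2 in batch 1 (shRNA 4 and shRNA 6) and 3 in batch 2 (shRNA 2, shRNA 5 and shRNA 6), and 4 control infections, with GFP and LacZ in each batch. In batch 1 the reads recovered per infection, summed over technical replicates, in megareads (M) came to 159.3 M for shRNA 4, 157.9 M for shRNA 6, 117.5 M for GFP and 57.5 M for LacZ. In batch 2 they came to 95.5 M for shRNA 2, 129.0 M for shRNA 5, 72.1 M for shRNA 6, 127.3 M for GFP and 145.6 M for LacZ. CHD8 itself had 2195 to 19882 reads per library. The median gene differed by 0.06 to 0.18 on the log2 scale between the technical replicates of an infection, and by 0.23 between GFP and LacZ of batch 1.

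CHD8 was lower in each of the 5 knockdown infections than in any control infection. Its level was 11.0 ± 1.72 FPKM (SD, n = 5) in the knockdown infections and 25.3 ± 3.17 FPKM (SD, n = 4) in the controls, a log2 fold change of -1.13 (SE 0.14). The highest knockdown infection reached 12.3 FPKM and the lowest control 23.0 FPKM. Relative to the mean of the controls of its own batch, CHD8 stood at 45.4% with shRNA 4 and 35.7% with shRNA 6 in batch 1, and at 51.5% with shRNA 2, 51.2% with shRNA 5 and 36.4% with shRNA 6 in batch 2. The difference was -1.23 in batch 1 and -1.06 in batch 2 on the log2 scale, with an interaction adjusted p of 0.876. A two-sided exact permutation of the infections within batches gave p = 0.0167, the smallest value that its 60 arrangements can give. Across all genes, limma ranked CHD8 number 2 by p, with an adjusted p of 0.158. The adjusted p was 0.0478 from the deposited log2 CPM (log2 fold change -1.35) and 0.0407 with limma-voom on the recovered reads (-1.41).

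**Figure D1:**
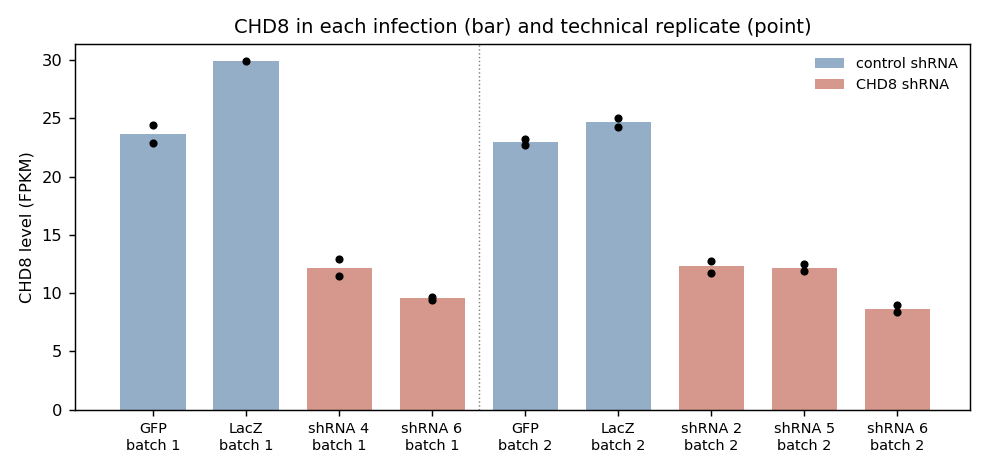
CHD8 level in FPKM in each infection, as bars from 0, with the technical replicates as points; blue bars are control shRNAs and red bars are CHD8 shRNAs, and the dotted line separates the batches. The 5 knockdown infections lie between 8.67 and 12.3 FPKM and the 4 control infections between 23.0 and 29.9 FPKM.

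Among the genes higher in the knockdown infections, BAALC, a gene of neuroectodermal tissue and of leukaemic blasts, stood at 144 ± 115 FPKM (SD, n = 5) against 34.0 ± 19.4 FPKM (SD, n = 4), a 4.16-fold difference on the log2(FPKM + 1) scale (log2 fold change 2.06, SE 0.30). The beta-tubulin TUBB6 was 1.73-fold higher, at 101 ± 11.3 FPKM (n = 5) against 58.2 ± 8.95 (n = 4). SCARB1, the receptor for high-density lipoprotein, was 1.70-fold higher, the DNA end-joining factor XRCC4 1.79-fold, the death-domain adaptor CRADD 1.67-fold, MYADM 1.59-fold and FAM127B 2.15-fold. RPL36A (1.73-fold) and the read-through transcript RPL17-C18orf32 (1.96-fold) are uncertain, as genes with paralogs or an overlapping gene. The log2 fold change of RPL17-C18orf32 turned from 0.97 to -0.15 in the deposited log2 CPM and to -0.17 in the recovered reads. Each of these 9 genes was higher than the controls of its batch in 5 of 5 knockdown infections.

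Among the genes lower in the knockdown infections, the laminin chain LAMA4 stood at 4.15 ± 1.47 FPKM (SD, n = 5) against 15.8 ± 7.46 FPKM (SD, n = 4), with a log2 fold change of -1.61 (SE 0.31). The astrocyte membrane protein gene MLC1 was at 8.58 ± 4.38 FPKM (n = 5) against 22.1 ± 6.70 (n = 4), a log2 fold change of -1.49 (SE 0.21). The neural cell adhesion molecule NCAM1 had a log2 fold change of -1.48 (SE 0.32) and SOX9, a transcription factor of neural stem cells and glia, one of -1.07 (SE 0.18). The histone demethylase KDM5B was at 26.6 ± 5.20 FPKM (n = 5) against 42.4 ± 2.34 (n = 4), with a log2 fold change of -0.69 (SE 0.15). The log2 fold changes of TSC22D3, a glucocorticoid-induced leucine zipper, the scaffold gene DLG5, the hypoxia-inducible factor inhibitor HIF1AN, the repressor HBP1, YY1AP1 and the retinoid receptor RXRB lay between -0.58 and -0.45. RP11-21J18.1 (-1.04) is uncertain, at -0.20 both in the deposited log2 CPM and in the recovered reads. Each of these 12 genes was lower in 5 of 5 knockdown infections.

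**Figure D2:**
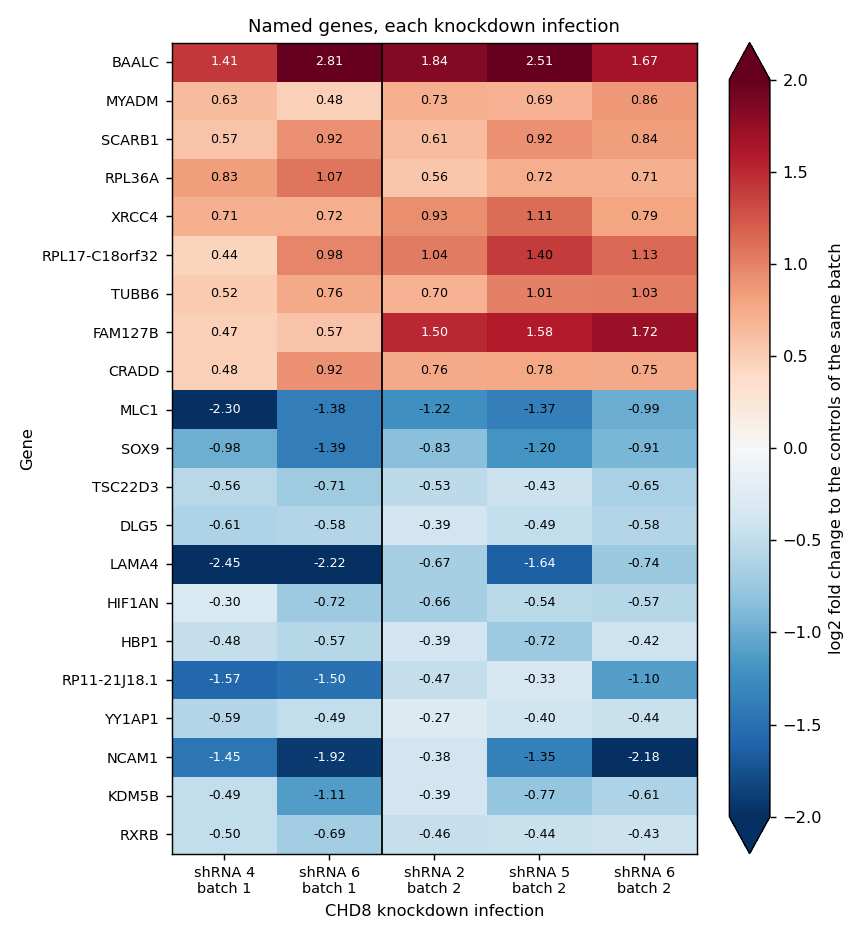
Log2 fold change of FPKM + 1 for each of 21 named genes (rows) in each of the 5 knockdown infections (columns) against the controls of the same batch; red is higher, blue is lower, and the line separates the batches. The 9 upper genes are positive and the 12 lower genes negative in each infection, from 2.81 for BAALC with shRNA 6 of batch 1 to -2.45 for LAMA4 with shRNA 4.

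No gene passed the adjusted threshold: limma called 0 of 15875 genes over both batches, with a smallest adjusted p of 0.158, while 1619 genes (987 higher and 632 lower) lay at an unadjusted p under 0.05, where 794 are expected by chance. The named genes thus differ in size and direction without passing correction. Limma on the deposited log2 CPM and limma-voom on the recovered reads each called 1 gene, CHD8, with 2258 and 2299 genes at an unadjusted p under 0.05. The split of higher and lower genes moved with the scaling, to 652 higher and 1062 lower with FPKM scaled to an equal upper quartile, 686 and 855 without the trend with GC content, and 1053 and 1246 with the recovered reads. With the technical replicates kept apart and the infection as a random effect, 26 genes passed (12 higher and 14 lower), and with the LacZ infection of batch 1 left out the unadjusted count was 967.

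In the authors' deposited table, 369 genes had an adjusted p under 0.05, 286 higher and 83 lower in the knockdown, and CHD8 had a log2 fold change of -1.35 with an adjusted p of 3.6e-06. Of these 369 genes, 98.6% had the same sign in the fit per infection and 271 lay at an unadjusted p under 0.05 there. Across genes, the fold changes of the authors' deposited table correlated with those computed here at r = 0.818 from FPKM and 0.976 from the log2 CPM; genes are not independent replicates. Of the 12 named higher and 12 named lower genes, 8 and 5 had an adjusted p under 0.05 in the authors' deposited table. For the 280 genes higher in the authors' deposited table that had a GC value, the median log2 fold change in FPKM was 1.38 in batch 1 and 0.11 in batch 2.

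Of the 24 gene lists, 4 were lower and 1 was higher in the knockdown by camera with a preset correlation, and 0 with an estimated correlation (2 at an unadjusted p under 0.05) or by fry (1 at an unadjusted p under 0.05). The 63 measured chromatin regulators had a median log2 fold change of -0.09 (46 members negative and 17 positive, adjusted p = 0.00049, and 0.742 with an estimated correlation), with KDM5B at -0.69, the remodeller CHD6 at -0.47 and ARID1B at -0.28, and the deacetylase HDAC4 at 0.66, but 0.10 in the recovered reads and 0.18 in the deposited log2 CPM. The 20 measured replication-dependent histones had a median of -0.30 (17 negative, adjusted p = 0.00049, and 0.767 with an estimated correlation). HIST1H2BD had a log2 fold change of -0.64, HIST2H2BE -0.94, HIST1H2AE -0.82 and the linker histone HIST1H1C -0.83; histone genes are near-identical copies, so single members are uncertain. The 28 p53 targets had a median of -0.18 (21 negative, adjusted p = 0.02, and 0.917 with an estimated correlation), with the apoptosis effector BAX at -0.51 and TP53INP1 at -0.71, while the stress cytokine GDF15 was at 1.64. The 9 CHD family genes had a median of -0.13 (adjusted p = 0.02, and 0.566 with an estimated correlation), led by CHD8. Without CHD8 itself the adjusted p was 0.134. Most members of the CHD family list, CHD6 among them, are also on the list of chromatin regulators, so these calls are not separate. KDM5B and ARID1B are likewise on both the chromatin regulator list and that of the ASD risk genes. The 24 genes of cholesterol biosynthesis had a median of 0.15 (21 positive, adjusted p = 0.0203, and 0.917 with an estimated correlation), with SC5DL, a sterol desaturase, at 0.82, DHCR7 at 0.61, MVD at 0.77 and MSMO1 at 0.33.

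The median of the chromatin regulators was negative in 4 of 5 knockdown infections and that of the histones in 3 of 5, with 0.03 for shRNA 2 and 0 for shRNA 6 of batch 1. That of the p53 targets was negative in 3 of 5 (0.03 with shRNA 2 and 0.17 with shRNA 4), that of the CHD family in 4 of 5, and that of cholesterol biosynthesis was positive in 3 of 5 (-0.10 with shRNA 4 and -0.30 with shRNA 6 of batch 2). In the deposited log2 CPM the calls of the chromatin regulators (adjusted p = 0.0567), p53 targets (0.0603) and cholesterol biosynthesis (0.0567) were absent, and with limma-voom that of the p53 targets (0.0547). The p53 call was absent without the shRNA 6 infection of batch 1 (adjusted p = 0.641), without GFP of batch 1 (0.0699) or without GFP of batch 2 (0.0707). The cholesterol call was absent without shRNA 2 (0.207), shRNA 5 (0.149), shRNA 6 of batch 1 (0.119) or GFP of batch 2 (0.139), and that of the CHD family without GFP of batch 2 (0.063).

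**Figure D3:**
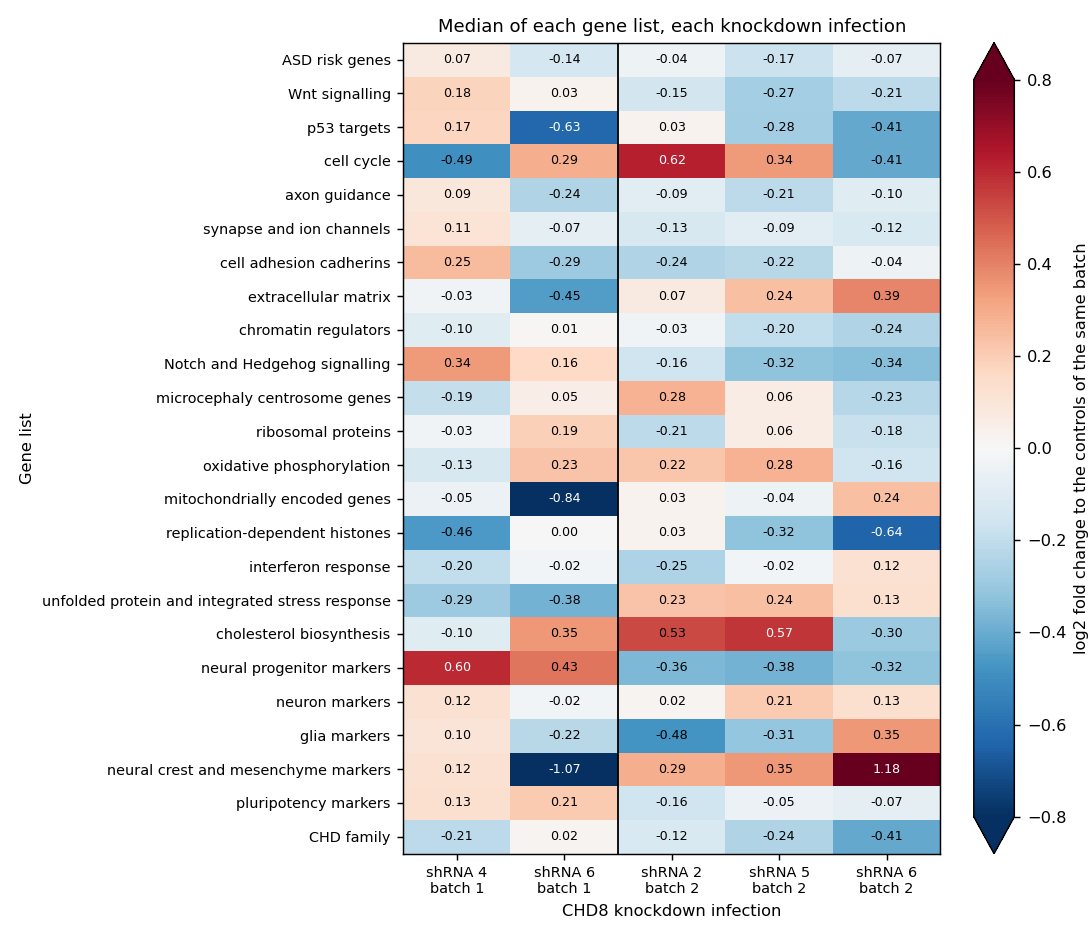
Median log2 fold change of each of the 24 gene lists (rows) in each of the 5 knockdown infections (columns) against the controls of the same batch; red is higher, blue is lower, and the line separates the batches. The cell cycle list ran from -0.49 with shRNA 4 to 0.62 with shRNA 2, and neural crest and mesenchyme markers from -1.07 to 1.18 with shRNA 6 in batch 1 and batch 2.

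The ASD risk genes, 47 of them measured, had a median of -0.06 with 29 negative and 18 positive (adjusted p = 0.08, and 0.917 with an estimated correlation). The list passed with limma-voom (adjusted p = 0.0362), without shRNA 4 (0.0366) and without GFP of batch 2 (0.0294). Over all genes tested 0 of them passed the adjusted threshold with limma, and 0 with limma-voom. With limma, 5 lay at an unadjusted p under 0.05, and 2 passed when adjusted over the list alone. KDM5B had a log2 fold change of -0.69, the sodium channel gene SCN2A -0.66 at 0.149 ± 0.0709 FPKM (n = 5) against 0.897 ± 0.495 (n = 4), the zinc finger gene POGZ -0.44 and ARID1B -0.28, each lower in 5 of 5 infections. Axon guidance genes had a median of 0.01, with 26 positive and 23 negative (adjusted p = 0.204, and 0.917 with an estimated correlation). Among them, the ligands SLIT1 and SLIT3 had log2 fold changes of -1.69 and -0.91 and the receptor EPHB3 -1.02. SLIT1 was at -0.59 in batch 1 and -2.62 in batch 2, and EPHB3 at -0.58 and -1.38. The axon guidance list passed lower without shRNA 4 (adjusted p = 0.0427), without GFP of batch 1 (0.0488) and without the GC trend (0.0194). List passes under alternatives in this paragraph used camera at the preset correlation, and an estimated correlation was not run there. Among synapse and ion channel genes (median -0.07, adjusted p = 0.0894, and 0.566 with an estimated correlation), the scaffold DLG2 was at -1.10. That list passed lower without GFP of batch 2 (0.032) and without the GC trend (0.0401). Among cell adhesion genes and cadherins (median -0.06, adjusted p = 0.164, and 0.917 with an estimated correlation), the protocadherin PCDH19 was at -1.29 and FAT4 at 0.27. That list passed lower without GFP of batch 1 (0.0139). In the extracellular matrix list (median -0.03, adjusted p = 0.291), the proteoglycan NCAN was at -1.58 and the metalloproteinase inhibitor TIMP3 at -1.63, and 1 gene passed when adjusted over the list alone. Wnt signalling (median -0.09, adjusted p = 0.223) held WNT5A at -0.79 and the receptor FZD9 at 0.73. Notch and Hedgehog signalling (median -0.06, adjusted p = 0.164, and 0.926 with an estimated correlation) held DLK1 at 1.00 and HEY1 at -0.57. The latter list passed lower without shRNA 4 (0.023), without LacZ of batch 1 (0.022) and without the GC trend (0.0194).

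Markers of cell types gave no list call over the 9 infections. Neural progenitor markers had a median of 0.11 (adjusted p = 0.836), and 2 of the 23 measured passed when adjusted over the list alone. SOX9 was at -1.07, while ZIC5 and ZIC2 were at 1.45 (SE 0.34) and 1.71 (SE 0.55). ZIC2 stood at 47 FPKM in GFP of batch 1, above each knockdown infection (27.7 to 42.7), and at 2.45 to 11.1 in the other controls. ZIC5 stood at 10.9 FPKM in GFP of batch 1, within the range of the knockdown infections (6.86 to 12). Neuron markers had a median of 0.19 (adjusted p = 0.845), with the neurofilament gene NEFL at 1.14 and NHLH1, lower in 5 of 5 infections, at -0.42. Glia markers had a median of -0.12 (adjusted p = 0.387), with APOE at 1.18 and S100B at -0.61. Neural crest and mesenchyme markers had a median of 0.28 (adjusted p = 0.451, and 0.926 with an estimated correlation). At the preset correlation they passed higher without shRNA 6 of batch 1 (0.0239), where their median was -1.07 against 0.12 to 1.18 in the others. COL1A2 was at -0.49, TWIST1 at 0.43, TAGLN at 1.55 (-1.07 with shRNA 6 of batch 1, 1.74 to 2.85 with the others) and COL3A1 at 1.11 (3.46 with shRNA 6 of batch 2, 0.27 to 0.84 with the others; the COL3A1 log2 fold change without that infection was 0.60). Pluripotency markers had a median of -0.04 (adjusted p = 0.95), against a mean of 0.11; SALL4 was at -0.34 and LIN28A at 0.69, and at -0.28 with GFP controls only.

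The remaining lists were not called over the 9 infections either. Passes under alternatives below used camera at the preset correlation, and an estimated correlation was not run there. Over the 9 infections camera with an estimated correlation gave an adjusted p of 0.95 for ribosomal proteins and for oxidative phosphorylation. It gave 0.987 for the cell cycle and 0.926 for the interferon response. The cell cycle list had a median of 0.02 (adjusted p = 0.95) and passed higher without shRNA 4 (0.0366), with the licensing factor CDT1 at 1.14 (2.38 in batch 1 and 0.10 in batch 2, interaction adjusted p = 0.0507), UBE2C at 0.31, E2F8 at -0.28 and NUSAP1 at -0.26. Microcephaly and centrosome genes had a median of -0.02 (adjusted p = 0.463), with CDK6 at 0.56 and CASC5 at -0.46. Ribosomal proteins had a median of -0.01 (adjusted p = 0.298), with RPS4X at -0.55 and RPS2 at 0.35. They passed lower without shRNA 6 of batch 1 (0.00254), LacZ of batch 1 (0.0149) or both shRNA 6 infections (0.0187) and with upper-quartile scaling (0.0388). Oxidative phosphorylation had a median of 0.11 (adjusted p = 0.164), with COX8A at 0.74 and NDUFA1 at -0.32. That list passed higher without shRNA 4 (0.00708), shRNA 6 of batch 2 (0.00323), GFP of batch 1 (0.0342) or both shRNA 6 infections (0.0338). Mitochondrially encoded genes had a median of -0.15 (adjusted p = 0.0767), carried by shRNA 6 of batch 1: their median was -0.84 there and -0.05 to 0.24 in the others, and MT-CYB stood at -1.43 there and -0.29 to -0.04 in the others. Without that infection the list turned higher (adjusted p = 0.847). With it, the list passed lower without shRNA 4 (0.0318), shRNA 6 of batch 2 (0.00774), GFP of batch 2 (0.0262) or LacZ of batch 2 (0.0155). These passes are at the preset correlation of 0.01. Over the 9 infections the correlation was estimated at 0.793, and camera with it gave this list an adjusted p of 0.917. The interferon response had a median of -0.01 (adjusted p = 0.298), with STAT2 at -0.70 and DDX60 at 0.41, and passed lower without both shRNA 6 infections (0.0187). The unfolded protein and integrated stress response had a median of 0.01 (adjusted p = 0.774), with SDF2L1 at 0.86 and CTH at -0.47.

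The knockdown effect differed between the batches at 337 of 15875 genes by the interaction term in limma, 28 with a higher and 309 with a lower effect in batch 2. NDUFB7, a subunit of respiratory complex I, had a log2 fold change of 2.77 in batch 1 and 0.06 in batch 2 (interaction adjusted p = 0.0151), and AXIN1, a scaffold of the beta-catenin destruction complex, 1.37 and 0.07 (0.0328). KCNJ10, a glial potassium channel gene, had -0.04 and -0.99 (0.0151), the cystine transporter gene SLC7A11 -1.73 and 0.26 (0.0181), and FAM127B 0.52 and 1.60 (0.0353). KCNJ10 was near the floor in the batch 1 controls, at 0.039 FPKM in GFP and 0.0824 in LacZ, against 1.32 and 1.29 in batch 2. A fall of KCNJ10 in batch 1 could thus not be seen. The genes with a lower effect in batch 2 had a median transcript GC content of 64.4%, against 48.9% for the genes tested. Over genes with a mean of 1 FPKM or more, the level relative to the batch mean correlated with GC content at a rho of -0.259 in GFP and -0.162 in LacZ of batch 1, and at 0.167 with shRNA 4 and 0.182 with shRNA 6 there; in batch 2 the rho lay between -0.147 and 0.106. With the trend of each infection with GC content removed, 44 genes passed the interaction test, and without GFP of batch 2 46 did.

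**Figure D4:**
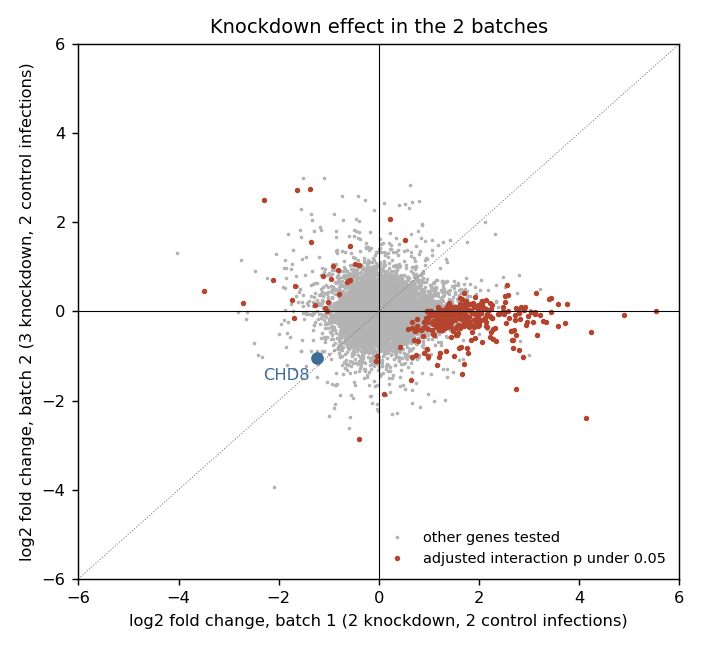
Log2 fold change of each of 15855 genes in batch 1 (horizontal, 2 knockdown and 2 control infections) and batch 2 (vertical, 3 knockdown and 2 control infections); red points are 336 genes with an adjusted interaction p under 0.05, grey points are other genes tested, and the dotted line marks equal effects. Most red points lie at positive values of batch 1 and near 0 in batch 2, and CHD8 lies at -1.23 and -1.06.

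By camera with a preset correlation, 9 lists differed between the batches, and 0 with an estimated correlation (2 at an unadjusted p under 0.05, against 10 with the preset value). The unfolded protein and integrated stress response list had a median log2 fold change of -0.36 in batch 1 and 0.24 in batch 2 (interaction adjusted p = 1.3e-08, and adjusted p = 0.379 with an estimated correlation). Extracellular matrix genes had -0.28 and 0.18 (0.000157, and 0.492 with an estimated correlation as adjusted p), and mitochondrially encoded genes -0.48 and 0.10 (0.000262, and 0.697). Notch and Hedgehog signalling had 0.18 and -0.27 (0.00128, and 0.492), and ribosomal proteins 0.10 and -0.12 (0.00809, and 0.893). The other 4 lists were the cell cycle, Wnt signalling, neural progenitor markers, and neural crest and mesenchyme markers, with interaction adjusted p-values from 0.0273 to 0.0345, and 0.893, 0.379, 0.492 and 0.697 with an estimated correlation.

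Within batch 1 alone, limma called 5 genes, all higher in the knockdown, with 1636 genes at an unadjusted p under 0.05. They were SCAND1 (log2 fold change 4.90), MZT2B (4.23), AL049836.1 (4.14), C5orf38 (3.57) and AC009133.19, which is listed at or next to 0 in the controls; these names were chosen after the values were seen. In batch 2 SCAND1, MZT2B, AL049836.1 and C5orf38 stood at -0.08, -0.46, -2.38 and -0.33. Limma-voom on the recovered reads called 0 genes within batch 1. On simulated data the limma fit of batch 1 alone found 0% of the 4-fold changes. Leaving out 1 infection of batch 1 leaves a lone infection in a group, so it cannot decide whether the 5 calls hold. Within batch 2 alone, limma called 0 genes, with 2057 at an unadjusted p under 0.05 and a smallest adjusted p of 0.18.

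The same hairpin was used in both batches as shRNA 6, each time against controls of its own batch. Across 15875 genes its fold changes in the batches correlated at a Pearson r of -0.075 and a Spearman rho of -0.044, although CHD8 stood at 35.7% and 36.4% of the controls. The 5 pairs of different hairpins across batches gave r from -0.227 (shRNA 4 with shRNA 2) to 0.146 (shRNA 6 of batch 1 with shRNA 2). With the deposited log2 CPM the r of shRNA 6 was 0.028, and with the recovered reads 0.041.

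GFP and LacZ controls were compared as infections without an effect of CHD8. Between them limma called 0 of 15875 genes, with 1211 at an unadjusted p under 0.05 (617 higher and 594 lower in GFP) and a smallest adjusted p of 0.371. This fit has 1 residual degree of freedom and found 0% of the simulated 4-fold changes, so its 0 calls give no background. Limma on the deposited log2 CPM called 43 and limma-voom 34, where each called 1 gene for knockdown against control. In the controls, PCDH19 was at 3.58 on the log2(FPKM + 1) scale in GFP of batch 1 and between 4.80 and 4.99 in the other 3 control infections, and the neurofilament gene NEFM was at 4.82 against 1.44 to 1.84. The difference of GFP from LacZ correlated between the batches at r = 0.265 across genes.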

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

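The removal of the trend with GC content, the splits for the p53, CHD family and cholesterol lists, the comparison with the unit of the authors' calls and the test of shRNA 6 at the interaction genes were tests chosen only after the results were seen.

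In 272 groups of 4 or 5 infections, 11 held 1 infection that stood far from the others, where about 14 are expected by chance. Among the knockdown infections, as log2 fold change to the controls of the same batch, these were shRNA 6 of batch 1 for RXRB (-0.69, others -0.50 to -0.43), MT-CYB (-1.43, others -0.29 to -0.04), TAGLN (-1.07, others 1.74 to 2.85) and the median of the mitochondrially encoded genes (-0.84, others -0.05 to 0.24). For shRNA 4 they were IFI27 (0.01, others -0.78 to -0.59) and the median of the synapse and ion channel list (0.11, others -0.13 to -0.07), and for shRNA 6 of batch 2 COL3A1 (3.46, others 0.27 to 0.84). Among the controls, as log2(FPKM + 1), GFP of batch 1 stood apart for PCDH19 (3.58, others 4.80 to 4.99), NEFM (4.82, others 1.44 to 1.84) and the median of the neural crest and mesenchyme markers (2.10, others 3.05 to 3.21). LacZ of batch 1 stood apart for MT-ND2 (11.02, others 11.40 to 11.44).

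The interaction test found 5 of the named genes and 9 lists with a knockdown effect that differed between the batches; with an estimated correlation 0 lists passed, with an adjusted p of 0.379 to 0.893 for the 9. On the log2 scale, the effect in batch 2 minus that in batch 1 was 1.08 for FAM127B, -1.30 for AXIN1, -0.95 for KCNJ10, -2.71 for NDUFB7 and 1.98 for SLC7A11. KCNJ10 was near the floor in the controls of batch 1, where a fall could not be seen. As list medians it was -0.46 for Wnt signalling, 0.30 for the cell cycle, 0.70 for the extracellular matrix, -0.50 for Notch and Hedgehog signalling, -0.23 for ribosomal proteins, 0.60 for mitochondrially encoded genes, 0.66 for the unfolded protein and integrated stress response, -0.90 for neural progenitor markers and 1.10 for neural crest and mesenchyme markers.

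Relabelling the infections within batches gave as many as the real 337 interaction genes in 1 of 60 arrangements, the real one, and the highest other gave 314. The 20 arrangements that kept the groups of batch 1 apart, either way round, gave 99 to 337 and the other 40 gave 0 to 1, so the count turned on 3 partitions of batch 1, too few for a share under 0.05. FPKM as the unit was argued against by 426 genes with limma-voom on the recovered reads, 255 of them shared. GC content bias may account for much of it, but the test cannot decide. Without the GC trend of each infection 44 genes were left, and the median size went from 1.73 to 1.05 at a median SE of 0.27 and 0.26. In batch 1 the trend ran with the condition, at a rho of -0.259 and -0.162 in GFP and LacZ and 0.167 and 0.182 with shRNA 4 and shRNA 6. Its removal would thus also take away a knockdown effect on GC-rich genes. A difference between the controls cannot be told apart (controls differed more than knockdowns at 55.2% of the genes and 55.5% of all genes), nor can different shRNAs. At 100% of the 337 genes shRNA 6 differed in the same direction by at least 0.5 times as much, against 63.6% of all genes tested. Both shares come from a fit with its values among them. At the 531 genes of the fit without it, the share was 53.9%.

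The authors' deposited table held 369 genes past its adjusted threshold, where 1 value per infection gave 0. FPKM as the unit was argued against, because the deposited log2 CPM and the recovered reads gave at most 1 gene per infection. With technical replicates as separate libraries, the deposited log2 CPM gave 2398 genes, 317 of them among the 369. At an unadjusted p under 0.05 that fit gave 4918 genes, and the deposited log2 CPM with 1 value per infection gave 2258. The authors' deposited table held 1757, below both. Separate libraries as fitted here thus gave far more genes than the authors' deposited table at either threshold. They can raise the adjusted count, but the test cannot tell whether they did so in the authors' comparison. The model behind the deposited p-values is not given in the sources used here. The authors' comparison may also rest on knockdown libraries that were not analysed here, and this difference was not tested. Separate libraries as the cause thus stay a hypothesis, and no biological explanation was tested.

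Counts and lists were set against splits of the 9 infections, 100 of them with the real one included. The splits were drawn without regard to batch, with batch as a covariate in the fit, so some lie close to the batches. For the 0 genes past the adjusted threshold this tests nothing, as 100 of 100 splits must give as many, but the highest other gave 198 (shRNA 4, shRNA 6 of batch 2, GFP of batch 2 and both LacZ infections on 1 side), which points to a structure of the samples. As many genes at an unadjusted p under 0.05 (1619) came from 12 of 100, the highest other 3435, and as many lists (5) from 84 of 100, the highest other 13. A camera p as small came from 8 of 100 for the chromatin regulators (4.08e-05, smallest other 1.82e-07), 19 of 100 for the histones (2.73e-05, smallest other 5.85e-13), 43 of 100 for the p53 targets (0.00334, smallest other 1.35e-12) and 45 of 100 for cholesterol biosynthesis (0.00423, smallest other 1.79e-12), so chance could not be excluded for these counts and lists. The smallest other p of the chromatin regulators came from shRNA 6 of batch 1 grouped with all controls, against the other knockdown infections. The other splits as small had 4 knockdown infections on 1 side, or shRNA 2 and shRNA 6 of batch 1 with most controls. Such splits keep much of the knockdown contrast, so the share of 8 of 100 is not a measure of chance alone. For the CHD family, 3 of 100 gave a camera p as small (0.00267, smallest other 0.00218). That list holds CHD8, the gene that the shRNAs target, so a small p for the real split was built in. The split test therefore cannot exclude chance for the family, and without CHD8 the camera adjusted p was 0.134. Gene length was argued against, since the medians of the chromatin regulators and histones lay at percentiles 0.02 and 0.01 of 10000 random lists matched on exonic length and level, and an effect of CHD8 stays open.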

How the results depend on the processing

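The tests on log2 CPM, recovered reads, upper-quartile scaling, the GC trend, the replicate block, the random effect and without both shRNA 6 infections were chosen only after seeing the data. CHD8 was lower under every alternative run, from -0.97 without both shRNA 6 infections to -1.41. Where no cause is given below, the cause was not tested.

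For CHD8 knockdown against control, 0 genes passed, but 1619 did at an unadjusted p under 0.05 and 386 under 0.01, by the looser threshold. Technical replicates as separate libraries gave 1171 genes (3921 unadjusted; CHD8 -1.106, past the threshold), and in log2 CPM 2398 (4918; -1.354), by counting replicates of 1 infection as independent. With the letter as replicate block it was 850 (3672; -1.10), although the letters did not pair (median r -0.03 over 28 pairs of infections). With the infection as a random effect it was 26 (CHD8 -1.131), in log2 CPM 1 (CHD8 -1.351) and with voom 1 (CHD8 -1.406). The unadjusted count was 826 for genes at or above the median level (fewer genes tested), 709 with GFP controls only, and 967 to 2240 leaving out 1 infection, the lowest without LacZ of batch 1.

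Within batch 1, the 5 genes became 31 with pseudocount 0.1, 79 at or above the median level, 128 above the lower quartile, 1364 with separate libraries (2281 in log2 CPM), 195 in log2 CPM, 3 with upper-quartile scaling, and 0 with voom, without the GC trend, with GFP controls only, with LacZ controls only and without both shRNA 6 infections; leaving out 1 infection gave 0 to 0. A lone infection in a group was assumed to vary like the others. Since even the full fit of batch 1 found 0% of the simulated 4-fold changes, counts of 0 with a lone infection decide nothing. Within batch 2, the count was 2607 with separate libraries and 3210 in log2 CPM with separate libraries.

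The 337 interaction genes became 2750 with separate libraries (3381 in log2 CPM), 193 with 1 infection per hairpin, 2 with GFP controls only, 2 with LacZ controls only, 44 without the GC trend and 531 without both shRNA 6 infections. Leaving out 1 infection gave 46 to 374: 182 without shRNA 2, 86 without shRNA 5, 193 without shRNA 6 of batch 2, 69 without GFP and 129 without LacZ of batch 1, and 46 without GFP and 69 without LacZ of batch 2. GFP against LacZ gave 23 genes at or above the median level, 15 above the lower quartile, 1023 with separate libraries (1815 in log2 CPM), 43 in log2 CPM and 34 with voom; leaving out 1 infection left no residual degrees of freedom.

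The 5 lists became 0 with fry, 0 with an estimated correlation, 2 in log2 CPM, 8 without the GC trend and 4 to 11 leaving out 1 infection (11 without shRNA 4). The correlation of shRNA 6 between batches was 0.028 in log2 CPM and 0.041 in recovered reads. Among named genes, and lists that passed the threshold, these turned direction: the MT-CO2 log2 fold change (0.03 without shRNA 6 of batch 1; -0.223 to 0.03 leaving out 1 infection), LIN28A (-0.277) and LIN28B (-0.306) with GFP controls only, the LIN28B log2 fold change without LacZ of batch 2 (-0.056; -0.056 to 0.549 leaving out 1 infection), in log2 CPM (-0.05) and there with separate libraries (-0.089), RPL17-C18orf32 in log2 CPM (-0.149; -0.146 with separate libraries) and with voom (-0.174), and the cell cycle list (adjusted p 0.0366 without shRNA 4; 0.0366 to 0.836 leaving out 1 infection). Under this or other alternatives, lists that did not pass also turned direction: cell cycle, Notch and Hedgehog signalling, axon guidance, extracellular matrix, interferon response, microcephaly and centrosome genes, mitochondrially encoded genes, neural progenitor, neuron and pluripotency markers, ribosomal proteins, and the unfolded protein and integrated stress response. Of the other values for lists 428 kept their side of the threshold, 28 passed it newly and 24 no longer passed; for named genes 2697 kept it and 217 passed it newly.

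Not run were DESeq2 size factors, edgeR upper quartile, edgeR without a filter and the DESeq2 interaction, which need deposited counts, and the alternatives for the authors' calls alone. CHD8 had 2195 to 19882 reads per library at 33.4 to 88.9 megareads in all, and no alternative at a lower depth was run. On simulated data with 5 and 4 infections 20.9% of 1.5-fold and 89.4% of 4-fold changes were called.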

Other observations

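The relations below were chosen only after the data were seen.

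The median of the cell cycle list, as log2 level relative to the batch mean, was 0.52 with shRNA 2, -0.44 with shRNA 4, 0.18 with shRNA 5, and 0.36 and -0.54 with shRNA 6 in batch 1 and batch 2. Over the 9 infections it correlated with the median of the microcephaly and centrosome genes at r = 0.951 (exact permutation within batches p = 0.00104, adjusted over 23 lists 0.024). CENPE and CENPF are on both lists. With glia markers the r was -0.872 (exact permutation p = 0.00313, adjusted 0.0359), with cholesterol biosynthesis 0.863 (adjusted 0.0619) and with oxidative phosphorylation 0.841 (adjusted 0.0619). By Spearman rho none of these passed, with 0.9 for the microcephaly list (adjusted 0.0559) and -0.895 for glia markers (adjusted 0.0559).

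The genes higher in the authors' deposited table had a median transcript GC content of 64.2%, the lower ones 48.3%. Of the 280 higher genes with a GC value, 191 lay at an unadjusted p under 0.05 in the fit per infection and 134 without the GC trend, with a median log2 fold change of 0.73 and 0.40. Their median was 1.38 in batch 1 and 0.11 in batch 2.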
